A study of Homo sapiens with 7 samples.

How the data were processed

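Total RNA of 7 glioblastoma cell lines was measured on Agilent 1-colour expression arrays, 1 array per line. Per the labels' protocols the RNA was isolated with a Qiagen Allprep kit and labelled with Cy3 by the Agilent low input procedure, and the cells were at low passage from 2 suppliers, with A172, LN18, LN229, T98G and U87-MG from the first and U138-MG and U251-MG from the second. The array positions in the file names place A172, LN18, LN229 and T98G in the first row of 1 slide and U87-MG, U138-MG and U251-MG in the next.

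The deposited scanner files hold fluorescence intensity per spot, extracted with Agilent Feature Extraction 11.0.1.1 per the file headers. The processed intensity used here is background subtracted and detrended within the array by that software, per the file headers, with no normalization between arrays. The authors also deposited a table of log2 values for 22037 probes. The labels do not state how it was made. Its columns followed log2 of the mean spot intensity with Pearson's r between 0.995 and 1.000 across probes, and their medians lay between 8.73 and 8.79, as after quantile normalization without background subtraction. How its probes were chosen is not known. It served as an alternative source only.

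Each array had 62976 spots, of which 58717 were not controls and represented 50599 probes, 902 of them with 10 spots. Spots marked by the extraction software as outliers, and controls, were left out, log2 processed intensity was averaged over the spots of a probe, and the 75th percentile of the array over all non-control probes was subtracted. Genes were named by matching the accessions and symbols of the files to a RefSeq gene table (assembly GRCh38.p14). That gene table was used for names, for which genes are protein-coding and for finding Y-linked genes, never for coordinates. Of the probes, 30275 matched by accession, 3198 by symbol and 470 by an older symbol, 15145 kept the name of the file, and 1511 had none. Genes of the Y chromosome and RNAs of X inactivation were removed (196 probes). Coordinates are those of the files, on hg19. A gene was represented by its probe of highest mean, and 26233 of 35479 genes had 1 probe.

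The gene rules, gene lists, comparisons and alternatives were fixed before the data were examined, with some exceptions. Tests and genes named as such in the closing parts were chosen after seeing the data. So were the correlations over the lines of the first supplier and the floor described in the next sentence. A value not well above background, by the mark of the extraction software, was set to the lowest value of a probe well above background on that array wherever a difference is given as at least N-fold, and in the alternative named for it. With 1 array per line there were no replicates, no difference had a test across genes, and the number of arrays limits the precision. A gene counted as highest in a line if it was well above background there and at least 2 (log2, 4-fold) above each of the other 6 lines, and as lowest if at least 2 below each of them with all 6 well above background. Median shifts of gene lists were set against 10000 random lists of the same size matched on mean expression in 20 bins and called outside their central 99%. Members above background in no line were left out, and of 453 list members 450 were measured. Whole chromosomes were compared over genes well above background in all lines, with random gene sets and a smallest size of 0.2 (log2) before the median of the random sets was taken off. Correlations of 4 pairs of lists across the lines had exact permutation tests (two-sided) with Benjamini-Hochberg adjustment.

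The genes named were the 5 of largest gap among the highest and the 3 among the lowest genes per line that had a symbol and kept a difference of 2 (log2) after quantile normalization, 24 landmark genes of glioblastoma, and from each list members among the 3 of widest range across lines. The results of some of these genes are not reported here. The 34 lists covered receptor tyrosine kinase and PI3K genes, p53 and RB pathway genes, p53 target genes, 9p21 neighbours, DNA repair, proliferation, the mesenchymal, proneural and classical subtypes, neural stem cells, astrocytes, oligodendrocytes, neurons, fibroblasts and matrix, pericytes and smooth muscle, endothelium, immune cells, epithelium, regulators of the epithelial-mesenchymal transition, interferon response, antigen presentation of class I and class II, NF-kB cytokines, hypoxia response, glycolysis, cholesterol synthesis, endoplasmic reticulum and amino acid stress, NRF2 targets, the HOXA, HOXB, HOXC and HOXD clusters, cancer-testis antigens and long non-coding RNAs.

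Alternatives were quantile normalization, normexp background correction with an offset of 50 (limma 3.58.1), the 75th percentile over probes above background on all arrays, the table of the authors, only probes above background on all arrays, no background filter, the median of the probes of a gene, the mean of the other 6 lines, Spearman's rho, the floor, and each line left out of the panel. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data with an SD of 0.3 (log2). Of genes changed 8-fold, 91.2% of 34 higher and 100% of 33 lower ones were called among 35479 genes, of those changed 2-fold 0%, and of 35279 unchanged genes 0%. Each simulated gene had the same background mark in all lines, so these rates do not cover genes at background in some lines only. Of unchanged lists 1.86% of 700 were called and of lists shifted by 0.5 (log2) 100% of 20. Of unchanged chromosomes 0% of 154 were called, and 1 shifted by 0.4 (log2) was called.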

Results

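Total RNA of 7 human glioblastoma cell lines was measured on Agilent 1-colour arrays labelled with Cy3. Glioblastoma is the most aggressive glioma of the adult brain, and the lines U87-MG, U251-MG, U138-MG, T98G, A172, LN18 and LN229 are established models of it. Each line was measured on 1 array, with no treatment and no replicate culture. The comparisons were therefore between lines, and no difference between lines had a replicate check or a p-value across genes. The labels mention the copy number state of the lines, and the arrays hold RNA only. The arrays held 50599 non-control probes, of which 49.5% in U251-MG to 59.8% in LN18 were well above background. The 75th percentile of signal intensity was 946 in LN18 and lay between 291 and 377 in the other 6 lines. No spot was saturated. Within an array, the SD over replicate spots of a probe had a median of 0.045 to 0.066 on the log2 scale. This spread alone gave a 95% limit of 0.24 (log2, 1.18-fold) for a difference between 2 arrays, and it did not cover variation between cultures. Of 35479 genes, 26053 were well above background in at least 1 line and 15236 in all 7.

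Of the landmark genes of glioblastoma, MGMT, the DNA repair gene whose product removes alkyl groups from guanine, was well above background in LN18, T98G, U138-MG and U251-MG and not in A172, LN229 or U87-MG, and LN18 exceeded LN229 at least 150-fold. Its probe spans positions 131506282 to 131557499 of chromosome 10 (hg19). SOX2, a stem cell transcription factor, was well above background in A172, LN229 and U251-MG, and U251-MG exceeded LN18 at least 3191-fold. GFAP, the astrocyte intermediate filament (probe at 42987518 to 42987577 of chromosome 17), was well above background in U251-MG alone, at least 461-fold above the nearest other line. NES, an intermediate filament of neural progenitors, was measured in all 7 lines and spanned 768-fold, from LN18 to U251-MG. PROM1 was not well above background in any line.

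RB1, the cell cycle suppressor, was lowest in U87-MG, 2.52-fold below the median of the other 6 lines. NF1 was 7.27-fold higher in LN18 than in LN229. CDKN1A, which encodes the p53-induced cell cycle inhibitor p21, was highest in A172 and 9.88-fold lower in U251-MG. PDGFRA was not well above background in A172, and U251-MG exceeded A172 at least 297-fold. MET spanned 5.96-fold with its highest value in U138-MG, and EGFR spanned 3.04-fold between LN18 and LN229 on its brightest probe. Its 2 other probes did not both show this, and with the median of the 3 probes EGFR in LN229 lay 0.75 (log2) above the median of the other lines. MDM2, the ubiquitin ligase of p53, spanned 3.67-fold and CDK4 1.89-fold. TERT, the catalytic subunit of telomerase, was well above background in all 7 lines and highest in LN18, 5.44-fold above the median of the others. OLIG2 was well above background in A172, LN229 and U87-MG. VIM and CD44, a mesenchymal filament and a surface receptor, were bright in every line and spanned 2.35-fold and 2.0-fold. CHI3L1, a secreted marker of mesenchymal glioma, was 47.2-fold higher in U87-MG than in LN18, the nearest line. FN1, which encodes fibronectin, was highest in U138-MG and 187-fold lower in LN18.

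**Figure D1:**
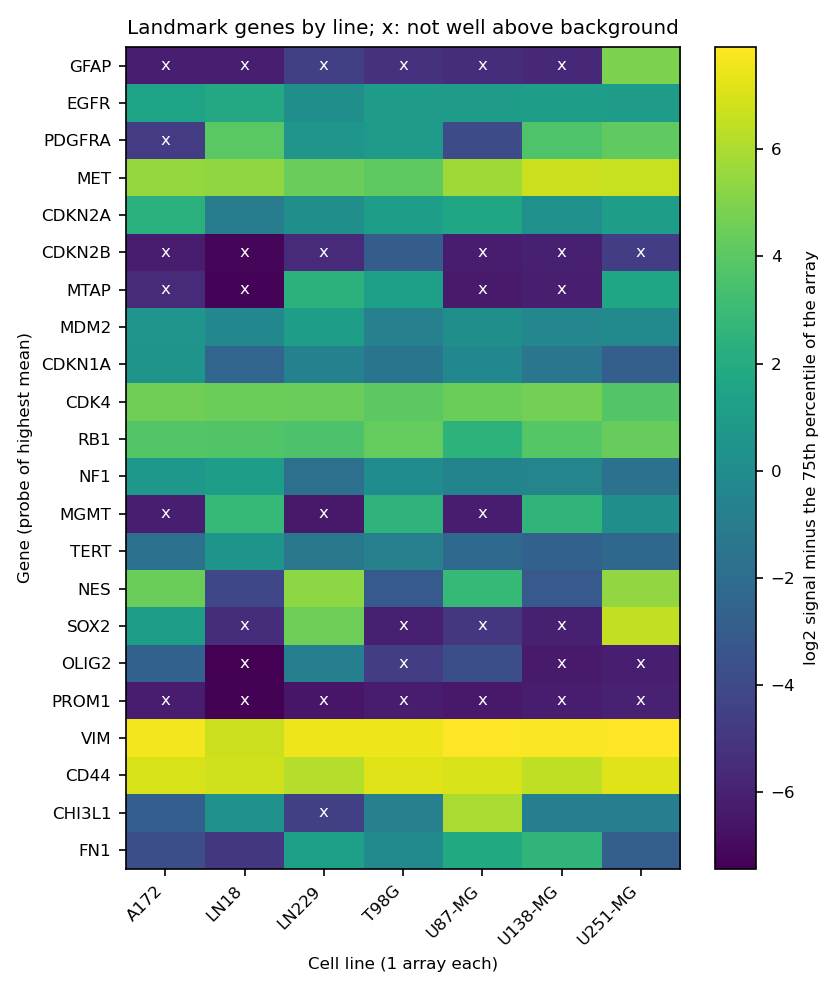
Colours give the log2 signal minus the 75th percentile of the array for landmark genes (rows) in the 7 lines (columns, 1 array each), and an x marks a value not well above background. GFAP has a value above background in U251-MG alone, whereas VIM and CD44 are bright in all 7 lines.

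The 9p21 region of chromosome 9 divided the lines. MTAP, a methionine salvage enzyme next to the CDKN2A locus, was well above background in LN229, T98G and U251-MG on its brightest probe and not in A172, LN18, U87-MG or U138-MG. Its 3 probes did not agree in all lines, since the probe at 21865830 to 21865889 was above background in A172 and not in T98G. FOCAD (probe at 20995798 to 20995857) was well above background in A172, LN229, T98G and U251-MG and was at least 437-fold lower in LN18 than the median of the other 6. KLHL9 (probe at 21331101 to 21331160) was measured in U138-MG too, 26.3-fold below that median, and was not above background in LN18 or U87-MG. Over the 7 of 8 measured 9p21 neighbours that were above background in at least 1 line, the median shift was above that of matched random lists by 4.73 (log2) in LN229, 3.56 in U251-MG, 2.13 in T98G and 2.0 in A172. It was below by -3.49 in LN18, -4.11 in U87-MG and -3.98 in U138-MG. With values below background set to the floor of their array these shifts were 4.08, 2.73, 1.27, 1.70, -3.26, -2.44 and -2.44. The shift in T98G changed sign when LN18, U87-MG or U138-MG was left out of the panel (-0.27, -0.27 and -0.32), and that in A172 then came to between 0.77 and 0.80, within the random lists. The shift in U87-MG was within them without LN229 or U251-MG (-0.75 and -0.76). With normexp background correction or the table of the authors, T98G (0.32 to 0.35) and U87-MG (-0.21 to -0.17) lay within the random lists too. CDKN2A itself was well above background in all 7 lines on its brightest probe, while its second probe was so in A172 alone, and CDKN2B was well above background in T98G alone.

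Genes set apart in 1 line by at least 4-fold numbered 2695 on the high side and 776 on the low side, where the rule for the low side alone asks for signal above background in all 6 other lines. Over probes above background on all arrays the split turned, to 277 and 342. U87-MG had the most genes that were highest in the line, 562, and T98G the fewest, 239, an order that turned under 2 of the settings below. A172 had 366, LN18 387, LN229 397, U138-MG 362 and U251-MG 382. Many of these were not protein-coding, in unequal shares. Protein-coding genes among the highest numbered 211 in A172, 200 in LN18, 238 in LN229, 110 in T98G, 265 in U87-MG, 128 in U138-MG and 178 in U251-MG. The lowest genes numbered 160 in LN18, 156 in U138-MG, 113 in A172, 107 in U87-MG, 96 in U251-MG, 73 in LN229 and 71 in T98G. The order of the first 2 was not firm. After quantile normalization 121 of the 160 in LN18 and 152 of the 156 in U138-MG were kept. Protein-coding genes among the lowest numbered 104 in LN18 and 136 in U138-MG, whereas at the floor LN18 had 145 lowest genes and U138-MG 95. With values below background at the floor of their array the counts of highest genes were 258 in A172, 255 in LN18, 276 in LN229, 145 in T98G, 367 in U87-MG, 240 in U138-MG and 240 in U251-MG. Background correction by normexp gave 171 highest genes in U87-MG and 81 in T98G, and the table of the authors 121 and 46, with LN229 (133) above the former and U138-MG (38) below the latter, and normexp and that table both lowered the counts of highest and lowest genes in all 7 lines by over 1.5 times. Over probes above background on all arrays LN229 (55), LN18 (50) and A172 (49) had more than U87-MG (40), and U138-MG (21) fewer than T98G (28). The table of the authors also differs in its normalization and holds fewer probes. Over the 149 named differences of at least 4-fold the median size was 7.30 (log2), against 4.92 with normexp, and over the 139 of them in the table of the authors it was 7.19, against 4.78 there.

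**Figure D2:**
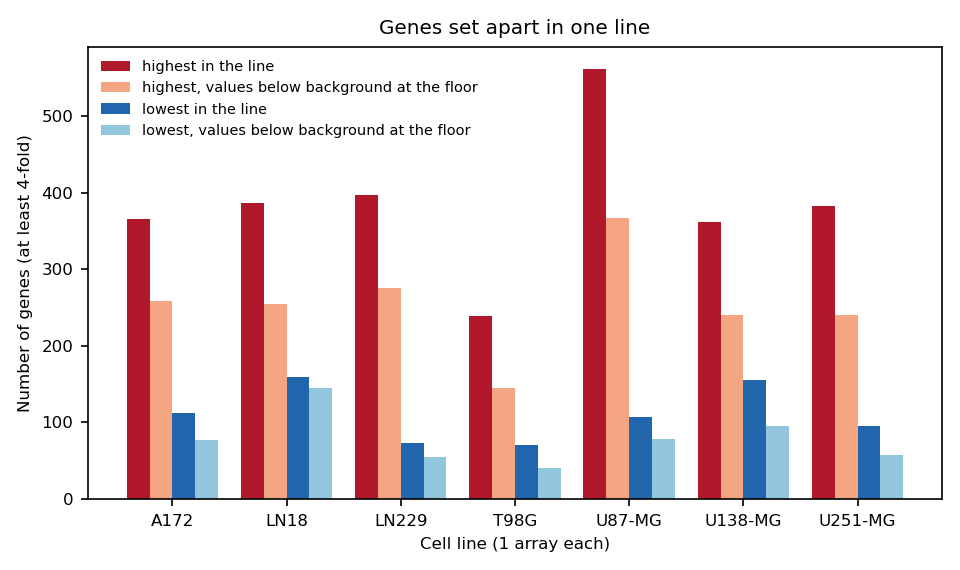
Bars give the number of genes at least 4-fold above the highest (red) or below the lowest (blue) of the other 6 lines, for each line (1 array each), and pale bars the same with values below background set to the floor of their array. U87-MG has the most highest genes in both, 562 and 367 with the floor, but not in the table of the authors (121, against 133 in LN229) or over probes above background on all arrays (40, against 55 in LN229).

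The genes named per line have large gaps to the nearest line, and a gap given as at least N-fold is a bound, so such genes have no firm order. In A172, MALL, a membrane raft protein gene (probe at 110841872 to 110841931 of chromosome 2), was at least 798-fold above the nearest other line. C19orf33, CLIC3 and COX7B2 were 334-fold, 279-fold and 232-fold above LN18, the nearest line, and the succinate receptor SUCNR1 was at least 161-fold higher and above background in A172 alone. Of the lowest genes, FUBP3 was 56.1-fold below the nearest line, ABL1 at least 50.9-fold and NEK9 39.8-fold. The second ABL1 probe, at another position of the gene, was not lower in A172.

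In LN18, GTSF1, a gene of the germline small RNA pathway (probe at 54849745 to 54849804 of chromosome 12), was at least 364-fold above the nearest line, and the neuropeptide receptor gene NPFFR2 and the cancer-testis gene SAGE1 were at least 70.1-fold and 52.8-fold above. BMP5, a bone morphogenetic protein, was 48.1-fold and LIPC, hepatic lipase, at least 37.2-fold above. The brightest probe assigned to MAP3K13, on a non-coding transcript, was at least 429-fold below the nearest line, with 6 of its 6 other detected probes in the same direction, and the antisense RNA HOXD-AS2 at least 186-fold. The ribosomal 5.8S transcript RNA5-8SN5 was 173-fold lower in LN18.

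In LN229 the transcription factor genes SOX10 (probe at 38369089 to 38369148 of chromosome 22) and SOX8 were at least 357-fold and 204-fold above the nearest line. EXTL1, a heparan sulfate enzyme gene, was 420-fold, the adhesion molecule CADM3 at least 180-fold and FXYD3, a regulator of the sodium pump, 179-fold above. Lowest in LN229 were the fucosidase gene FUCA2, at least 101-fold, the surface glycoprotein gene THY1, at least 69.3-fold, and the palmitoyltransferase gene ZDHHC2, at least 57.4-fold.

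In T98G, LYPD6B (probe at 150071079 to 150071138 of chromosome 2) was at least 47.3-fold higher, the carboxylesterase gene CES1 43.6-fold, the glutamate decarboxylase gene GAD2 at least 43.4-fold, MEI4 at least 41.9-fold and PYCARD, the inflammasome adaptor, 41.5-fold. PARD3, a polarity gene, was at least 87.2-fold lower on its brightest probe, and 1 of its 2 other detected probes went the same way. CMTM7 was 66.5-fold and the cytokine gene IL11 60.3-fold lower.

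In U87-MG, IL36B, a cytokine gene of the interleukin 1 family (probe at 113786522 to 113786581 of chromosome 2), was 609-fold above U138-MG, the nearest line, and the hyaluronan synthase gene HAS1 543-fold above A172. PNLIPRP3 was at least 361-fold, the BMP antagonist GREM1 156-fold and RRAD 130-fold higher. The basement membrane genes PXDN (probe at 1635659 to 1635717 of chromosome 2) and NID1 were at least 695-fold and 105-fold below the nearest line, and TUSC3 at least 65.3-fold.

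U138-MG had higher CAMKV by at least 58.4-fold, the small heat shock gene HSPB2 by 45.3-fold, MRPL23-AS1 by 40.8-fold and SEC16B by 39.6-fold. MRPL23-AS1 lost this difference with the median of its 3 probes, at -0.19 (log2) against the median of the other lines. LDOC1 (probe at 140269941 to 140270000 of the X chromosome) was at least 207-fold, ZDHHC12 123-fold and the ubiquitin ligase gene RNF135 at least 104-fold below the nearest line.

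U251-MG had the orphan receptor gene GPR141 (probe at 37780527 to 37780586 of chromosome 7) at least 1328-fold above the nearest line, GFAP at least 461-fold, TKTL1 189-fold, the neural transcription factor gene SOX3 107-fold and TSTD1 at least 104-fold. The forkhead gene FOXD1 was at least 95.9-fold, PERP, a p53 effector of cell adhesion, 91.3-fold and DUSP23 at least 79.4-fold lower than in the nearest line.

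Lists of genes fixed by function were compared in the same way. For each list and line, the median over members of the line minus the median of the other 6 lines was set against 10000 random lists matched on expression, and shifts are given relative to the median of those random lists. Of 238 pairs of list and line, 93 lay outside the central 99% of the random lists, 51 higher and 42 lower, against 2.38 expected, or 4.42 at the 1.86% of 700 simulated unchanged lists that were called. Both expectations are for lists of unrelated genes. Members of a list fixed by function can vary together, so the excess does not measure a departure from chance. With values below background at the floor of their array 82 did so, 81 of them shared. The median over all genes was shifted by -0.15 (log2) in LN18, -0.09 in LN229, 0.08 in U138-MG and 0.08 in U251-MG. Of the 93 shifts, 51 stayed outside the random lists in the same direction under all other settings that gave a value, and 41 of these also when each other line was left out in turn. Calls that ended under another setting or without a line are given with their values there.

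**Figure D3:**
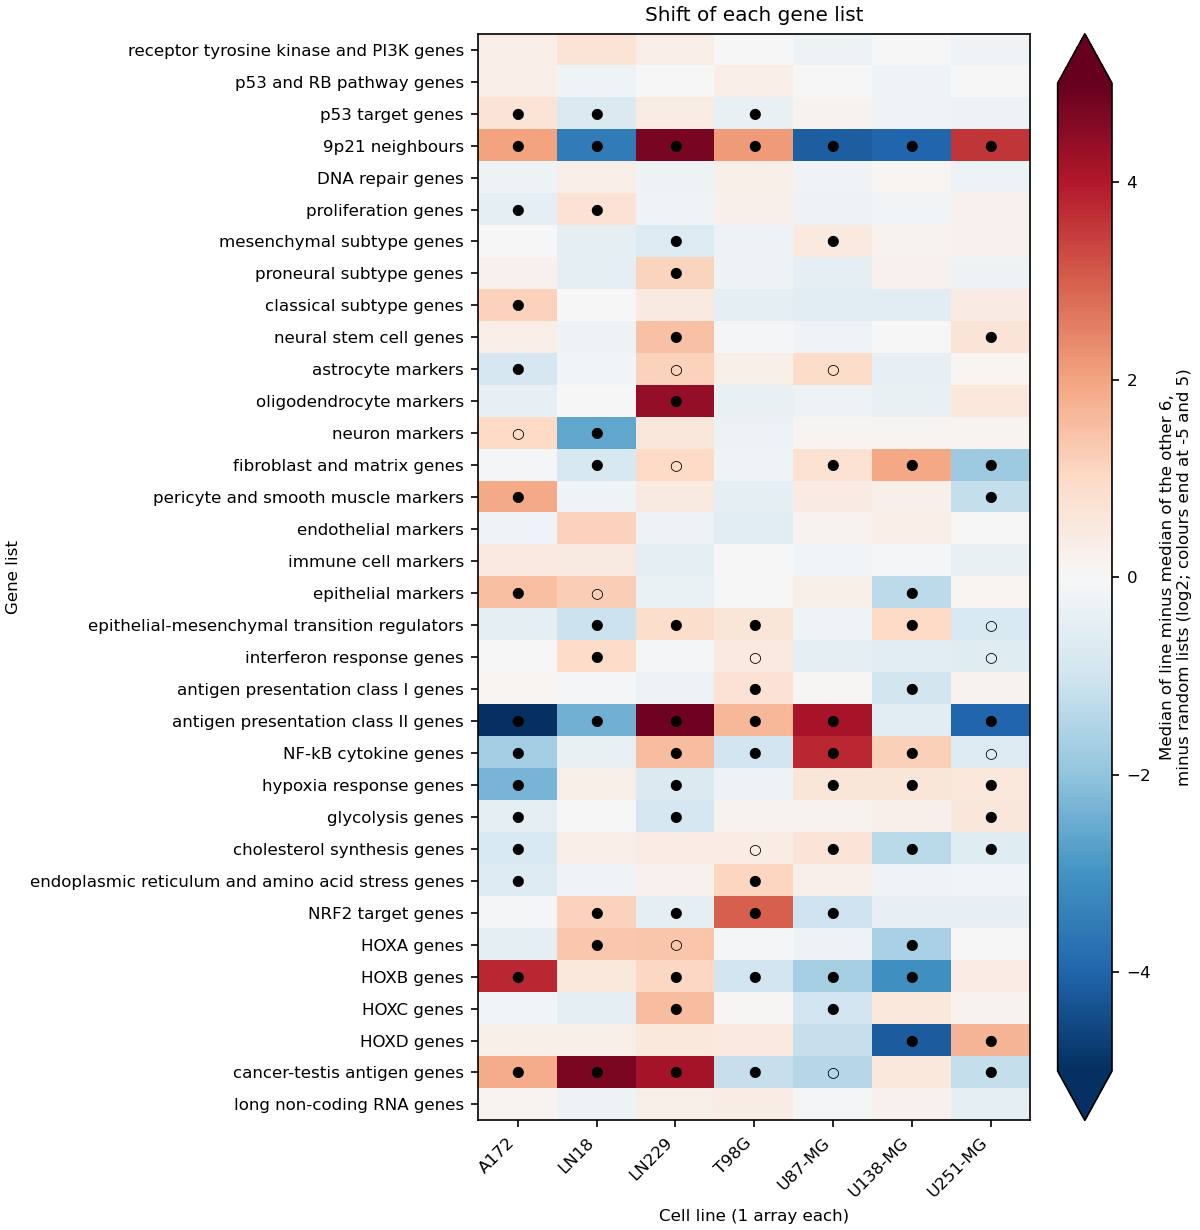
Colours give the shift of each of 34 gene lists (rows) in each line (columns, 1 array each) as log2 relative to matched random lists. Filled circles mark shifts outside the central 99% of the random lists with and without the background floor and open circles those outside it only without the floor, and the class II antigen presentation genes run from -5.66 in A172 to 4.85 in LN229.

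Genes of inflammation and antigen presentation differed between the lines. Antigen presentation class II genes, which display peptides to helper T cells, were higher by 4.85 (log2) in LN229 and 4.13 in U87-MG, and in each of these lines all 7 members were at least 2-fold above the median of the others. They were lower by -5.66 in A172 and -3.95 in U251-MG (-3.89 and -3.42 at the floor). LN18 at -2.40 was within the random lists without LN229, T98G or U87-MG (-0.33 to -0.27). T98G at 1.65 was within them with the median of the probes of a gene (0.74) and without A172, LN18 or U251-MG (0.78 to 0.86). HLA-DRA spanned at least 1463-fold, HLA-DPA1 1523-fold and HLA-DPB1 1292-fold, each with LN229 highest. NF-kB cytokine genes were higher by 3.75 in U87-MG, where 14 of 17 members were at least 2-fold above and 1 below (3.43 at the floor). IL1B was 124-fold and CXCL2 16.8-fold higher in U87-MG than in U138-MG, the nearest line, and the chemokine gene CXCL8 spanned at least 250-fold from A172 to U87-MG.

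The other shifts of the NF-kB cytokine genes depended on how dim members were treated. They were 1.54 (log2) in LN229, 1.21 in U138-MG, -1.72 in A172, -0.97 in T98G and -0.69 in U251-MG. Over the 7 members above background in all lines, A172 (0.07), LN229 (-0.10) and T98G (0.16) had the opposite sign. A172 was within the random lists with the table of the authors too (-0.30), while with the floor it was smaller and still outside them (-0.75). U138-MG was within them with normexp, with the table of the authors and over those 7 members (0.23 to 0.31), as were T98G (-0.14 to 0.16) and U251-MG, the latter also with the floor (-0.52 to -0.27). Without LN229, U87-MG or U138-MG, T98G (-0.45 to -0.38) and U251-MG (-0.44 to -0.16) were within the random lists. Interferon response genes were higher by 0.90 in LN18 and 0.49 in T98G and lower by -0.59 in U251-MG. LN18 was within the random lists under 3 other settings (0.62 to 0.80) and without A172, LN229, T98G, U138-MG or U251-MG (0.60 to 0.75), T98G under 7 settings (0.19 to 0.47) and without A172, U87-MG or U138-MG (0.15 to 0.33), and U251-MG under 6 settings (-0.49 to -0.09) and without any of the 6 other lines (-0.49 to -0.31). BST2 and IFITM1 spanned 252-fold and 234-fold from U87-MG to T98G, and IRF7 was at least 22.3-fold lower in U251-MG than in the nearest line. Antigen presentation class I genes were higher by 0.74 in T98G and lower by -0.92 in U138-MG.

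NRF2 target genes, which encode enzymes of detoxification and redox defence, were higher by 2.97 (log2) in T98G, with 12 of 13 members at least 2-fold above the median of the other lines, and by 1.16 in LN18. AKR1C1, AKR1C3 and AKR1B10, reductases of carbonyls and steroids, were 4.62-fold, 4.28-fold and 4.02-fold higher in T98G than in LN18, the nearest line. NRF2 targets were lower by -1.02 in U87-MG (-0.24 without A172, LN18 or T98G, within the random lists) and by -0.49 in LN229, which was within the random lists with no background filter, with the median of the probes of a gene (-0.49 to -0.38) and without A172, LN18 or T98G (-0.46 to -0.32). Endoplasmic reticulum and amino acid stress genes were higher by 1.09 in T98G, with ASNS, asparagine synthetase, 3.68-fold and CHAC1 3.92-fold above the nearest line. They were lower by -0.65 in A172, but within the random lists with the table of the authors and the median of the probes of a gene (-0.52 to -0.48).

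Hypoxia response genes were lower by -2.34 (log2) in A172, where 9 of 13 members were at least 2-fold below, and higher by 0.61 in U87-MG. They were lower by -0.72 in LN229 (-0.51 without U87-MG, within the random lists). Higher shifts of 0.59 in U138-MG and 0.52 in U251-MG were within the random lists with quantile normalization and over members above background in all lines (0.30 to 0.47, the table of the authors included, and 0.47 to 0.50). Both were so without A172, LN229 or T98G as well (0.22 to 0.23 and 0.23 to 0.25). CA9, a carbonic anhydrase, was well above background in LN18, U87-MG, U138-MG and U251-MG and spanned at least 154-fold. ANGPTL4 spanned at least 819-fold, with U138-MG highest. Glycolysis genes were lower by -0.85 in LN229 and higher by 0.56 in U251-MG. Lower glycolysis genes in A172 (-0.46) were within the random lists against the mean of the other lines (-0.09) and without T98G (-0.34). LDHA went the other way in U251-MG, 31.4-fold below the nearest line, and HK2 was 6.71-fold lower in A172. Cholesterol synthesis genes were lower by -1.33 in U138-MG, -0.78 in A172 and -0.62 in U251-MG and higher by 0.63 in U87-MG. The shift of 0.38 in T98G was within the random lists under 7 of 9 other settings (0.26 to 0.38) and without A172, LN18, U138-MG or U251-MG (0.13 to 0.39). HMGCS1, an early enzyme of the pathway, spanned 11.3-fold between U138-MG and LN18.

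Proliferation genes were higher by 0.71 (log2) in LN18 and lower by -0.46 in A172. LN18 was within the random lists with the median of the probes of a gene (0.51), and A172 without LN18 (-0.37). The mitotic topoisomerase gene TOP2A was 2.56-fold, CCNA2 2.38-fold and RRM2 2.99-fold higher in LN18 than in the nearest line, but RRM2 was at -0.21 (log2) against the median of the others with the median of its 3 probes. The p53 target genes were higher by 0.70 in A172, with 9 of 25 members at least 2-fold above, and lower by -0.73 in LN18, with 11 at least 2-fold below and 5 at least 2-fold above. A shift of -0.38 in T98G was within the random lists with the table of the authors and against the mean of the other lines (-0.32 to -0.26), and without A172, LN18, LN229 or U251-MG (-0.22 to -0.08). GDF15, a stress cytokine, was highest in T98G and 15.7-fold lower in U138-MG than in the nearest line. The lists of receptor tyrosine kinase and PI3K genes, of p53 and RB pathway genes and of DNA repair genes lay within the random lists in all 7 lines. CDKN2C, a member of the second, was well above background in A172, LN18 and U138-MG and not in the other lines.

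Oligodendrocyte markers were higher by 4.40 (log2) in LN229, with 7 of 10 members at least 2-fold above and 1 below (3.97 at the floor), among them SOX10. Neural stem cell genes were higher by 1.48 in LN229. A shift of 0.66 in U251-MG was within the random lists under 4 other settings (0.21 to 0.49) and without U87-MG or U138-MG (0.42 to 0.44). Proneural subtype genes were higher by 1.09 in LN229 (0.56 without U87-MG, within the random lists) and lower by -0.96 in LN18 at the floor alone. Classical subtype genes were higher by 1.17 in A172 (0.46 without U138-MG, within the random lists). Mesenchymal subtype genes were higher by 0.49 in U87-MG and lower by -0.67 in LN229, the latter within the random lists against the mean of the other lines (-0.37). Neuron markers were lower by -2.60 in LN18, where 9 of 11 members were at least 2-fold below. Their shift of 1.01 in A172 was within the random lists under 4 other settings (0.03 to 0.39) and without LN18, T98G or U251-MG (0.23 to 0.76). NEFL, a neurofilament gene, was 9.94-fold higher in A172 than in the nearest line. Astrocyte markers were lower by -0.86 in A172 (-0.70 over members above background in all lines, within the random lists). Their shift of 1.13 in LN229 was within the random lists under 6 other settings (-0.25 to 0.40). It was below 0 over members above background in all lines (-0.25), against the mean of the other lines (-0.08) and at the floor (-0.09). The shift of 0.90 in U87-MG was so at the floor and against the mean (0.22 to 0.48) and without A172 or T98G (0.57 to 0.58). S100B was 14.6-fold higher in LN229 than in the nearest line.

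Fibroblast and matrix genes were higher by 1.93 (log2) in U138-MG, with 9 of 16 members at least 2-fold above and 2 below. The collagen gene COL1A2 was 18.8-fold lower in LN229 than in the nearest line and 1527-fold below U138-MG. The list was lower by -1.83 in U251-MG, but by -1.05 at the floor and at 0.18 over the members above background in all lines. It was lower by -0.78 in LN18 (-0.63 with quantile normalization, and -0.62 to -0.52 without LN229 or U138-MG, within the random lists). Higher shifts were 0.78 in U87-MG (0.33 over members above background in all lines, and 0.39 to 0.43 without LN18, T98G or U251-MG) and 0.98 in LN229 (0.15 to 0.44 under 4 other settings and 0.39 without U251-MG), the bracketed values being within the random lists. Pericyte and smooth muscle markers were higher by 1.89 in A172 and lower by -1.18 in U251-MG. TAGLN, an actin-binding protein gene, was 34.6-fold higher in U138-MG than in A172, the nearest line. Epithelial markers were higher by 1.51 in A172 and 1.24 in LN18 and lower by -1.29 in U138-MG. LN18 was within the random lists under 6 other settings (0.23 to 1.08) and without LN229, U138-MG or U251-MG (0.47 to 0.49), and U138-MG with normexp, the table of the authors and no background filter (-0.67 to -0.23). The keratin gene KRT18 spanned 457-fold between A172 and U138-MG. Endothelial and immune cell markers lay within the random lists in all lines. CD68, a lysosomal protein gene of macrophages, was 5.40-fold higher in U87-MG than in the nearest line.

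Regulators of the epithelial-mesenchymal transition were higher by 1.00 (log2) in U138-MG. They were higher by 0.88 in LN229 and 0.61 in T98G, which were within the random lists with the median of the probes of a gene (0.49 in LN229) or also against the mean (0.25 to 0.33 in T98G), and without LN18 or T98G (0.53 to 0.72) and without A172, U87-MG or U251-MG (0.51 to 0.56) in turn. They were lower by -1.08 in LN18 and -0.76 in U251-MG. LN18 was within the random lists over members above background in all lines (-0.76) and without T98G or U138-MG (-0.55 to -0.24), and U251-MG under 3 other settings (-0.52 to -0.38) and without LN229, T98G, U87-MG or U138-MG (-0.42 to -0.21). PRRX1, a mesenchymal homeobox gene, was at least 7.00-fold lower in LN18 than in T98G, the nearest line.

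HOXB genes, which encode transcription factors of positional identity, were higher by 3.77 (log2) in A172, with 7 of 9 members at least 2-fold above, and lower by -3.08 in U138-MG, with 8 at least 2-fold below (-2.03 at the floor). HOXB8 was 16.7-fold higher in A172 than in the nearest line. They were higher by 1.03 in LN229 (0.85 without U138-MG, within the random lists) and lower by -1.67 in U87-MG and -0.96 in T98G. With normexp or the table of the authors U87-MG (-0.65 to -0.58) and T98G (-0.40 to -0.39) were within the random lists, and T98G also without A172, LN18, LN229, U87-MG or U251-MG (-0.53 to -0.28). HOXD genes were lower by -4.16 in U138-MG (-3.06 at the floor) and higher by 1.69 in U251-MG, the latter within the random lists without LN229, U87-MG or U138-MG (0.84 to 0.98). HOXA genes were lower by -1.63 in U138-MG. Higher HOXA shifts were 1.35 in LN18 (0.46 with the table of the authors, and 1.1 to 1.15 without A172, U87-MG or U138-MG, within the random lists) and 1.39 in LN229 (0.07 to 0.21 under 3 other settings, among them the floor). HOXC genes were higher by 1.54 in LN229, with 7 of 8 members at least 2-fold above. They were lower by -0.96 in U87-MG, within the random lists with the table of the authors and no background filter (-0.59 to -0.58) and without LN229, U138-MG or U251-MG (-1.0 to -0.69). HOXC9 was 16.0-fold lower in U87-MG than in the nearest line.

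Cancer-testis antigen genes, normally restricted to germ cells, were higher by 4.71 (log2) in LN18, with 9 of 11 members at least 2-fold above, and by 4.15 in LN229 (4.41 and 3.09 at the floor). CTAG2 spanned at least 637-fold and MAGEA12 at least 560-fold, both with LN18 highest. They were higher by 1.86 in A172 (0.58 with normexp, within the random lists) and lower by -1.16 in T98G, -1.20 in U251-MG (-0.27 without LN229, within the random lists) and -1.43 in U87-MG. U87-MG was within the random lists under 3 other settings (-0.57 to -0.34) and without A172, LN18, LN229 or U138-MG (-0.66 to -0.42). Long non-coding RNA genes lay within the random lists in all lines, and H19, an imprinted RNA, was 6.17-fold higher in LN229 than in A172, the nearest line.

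Over all genes above background in at least 1 line, the 21 pairs of lines correlated with Pearson's r between 0.858 and 0.907, a correlation across genes, which are not independent replicates. LN18 and T98G (0.907), LN229 and U251-MG (0.906) and A172 and T98G (0.906) were closest, and LN18 and U87-MG were most distant (0.858). U87-MG and U138-MG (0.901) were closer than LN18 and T98G with normexp (0.931 against 0.929) and over probes above background on all arrays (0.928 against 0.921). Over the 1000 genes of highest SD, LN18 and T98G (0.43), U87-MG and U138-MG (0.39) and LN229 and U251-MG (0.35) stood above the median of 0.16, and LN18 and U251-MG were lowest at 0.06, next to LN18 and U87-MG at 0.08. These last 2 pairs changed order with normexp (0.141 and 0.114), in the table of the authors (0.181 and 0.152), over probes above background on all arrays (0.386 and 0.305) and at the floor (0.069 and 0.064). Spearman's rho over those genes lay between 0.07 and 0.42.

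Whole chromosomes were compared because the labels point to copy number, and no table of chromosome arms was used here. Over the 15236 genes above background in all lines, 92 of 161 pairs of chromosome and line lay beyond random gene sets, against 0.322 expected for sets of unrelated genes. Of these, 29 were also at least 0.2 (log2) in size before the random median was taken off, as the rule fixed for them asks, and were called, 15 higher and 14 lower. The largest shifts relative to random sets were on chromosome 14 (0.48 log2, 1.39-fold, over 473 genes) and chromosome 18 (0.41, 1.33-fold, over 211 genes) in U138-MG. Chromosome 13 (0.33) and chromosome 22 (0.31) were higher in T98G, the X chromosome (0.31) and chromosome 17 (0.24) in U251-MG, and chromosomes 14 (0.31) and 4 (0.29) in LN18. Lower shifts were called for chromosome 21 in U138-MG (-0.34), chromosomes 14 (-0.31) and 22 (-0.30) in A172, chromosome 14 in T98G (-0.29), chromosome 16 in U251-MG (-0.29) and chromosome 19 in LN18 (-0.27). Relative to random sets 11 of the 29 were under 0.2, down to 0.11 for chromosome 3 in U138-MG. Of the 63 beyond random sets and not called, 7 were at least 0.2, among them chromosomes 12 (-0.28) and 13 (-0.28) in U251-MG, chromosome 22 in LN229 (0.26) and the X chromosome in U138-MG (-0.25). The shifts of chromosome 17, chromosome 15 (0.20) and the X chromosome in U251-MG were called under all 9 other settings and without any 1 line. Among these settings, the floor and only probes above background on all arrays cannot change a chromosome shift, by construction.

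With no background filter 9 of the 29 chromosome shifts were called again in the same direction, and the split became 6 higher and 9 lower of 15. The 20 not called again included chromosome 14 in U138-MG (0.07), A172 (-0.08) and T98G (-0.13), chromosome 18 in U138-MG (0.04), chromosome 22 in A172 (-0.08) and T98G (0.14), chromosome 13 in T98G (0.07) and chromosome 19 in LN18 (-0.01). They also included 8 smaller shifts, of chromosomes 3 and 4 in U138-MG, 6 in U87-MG, 9 in A172 and LN18, 15 and 19 in A172 and 21 in T98G, which lay between -0.08 and 0.09 there. Chromosome 4 in LN18 was not called under 5 settings (0.02 to 0.30) or without LN229, T98G or U251-MG (0.25 to 0.28), and chromosome 14 in LN18 not under 3 (0.11 to 0.30) or without A172 or T98G (0.26 to 0.27). Chromosome 16 in U251-MG was not called under 3 settings (-0.26 to -0.17) or without A172, T98G or U138-MG (-0.28 to -0.23). Chromosome 21 in U138-MG was not called under 3 settings (-0.31 to -0.11) or without A172, T98G, U87-MG or U251-MG (-0.31 to -0.28).

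**Figure D4:**
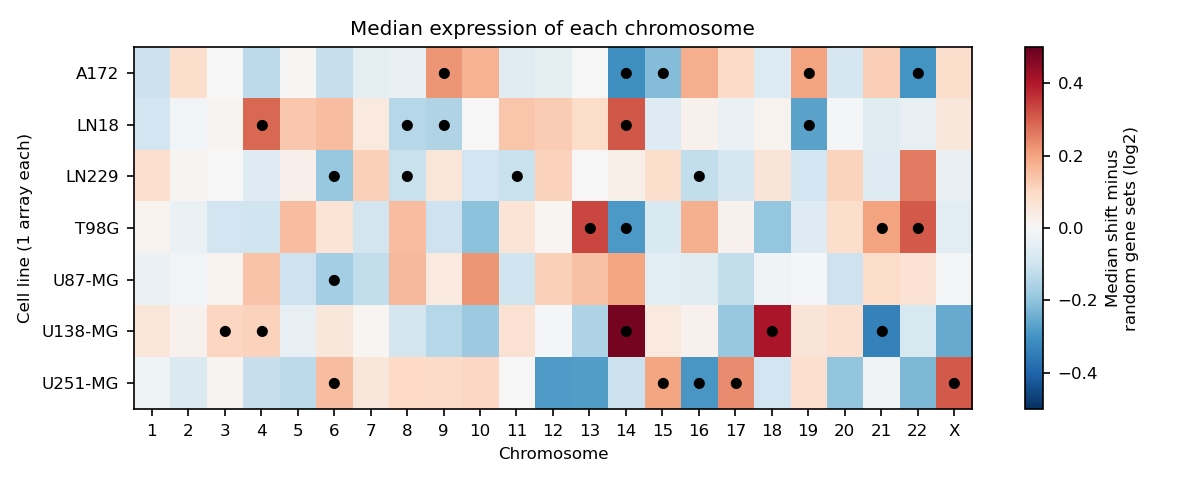
Colours give the median shift of the genes of each chromosome (columns) in each line (rows, 1 array each) as log2 relative to random gene sets of the same size; dots mark the 29 called shifts, beyond the random sets and at least 0.2 in size before the random median was taken off. Chromosome 14 is higher in U138-MG (0.48) and LN18 (0.31) and lower in A172 (-0.31) and T98G (-0.29).

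Of 4 relations between lists tested across the 7 lines, 1 passed the threshold after correction. The level of p53 target genes fell as that of proliferation genes rose, with Pearson's r = -0.94 (exact permutation p = 0.00238, adjusted p = 0.00952, two-sided, n = 7) and Spearman's rho = -0.96 (exact permutation p = 0.00278, adjusted p = 0.0111). Without LN229 and A172, the lines farthest from the median of the p53 target level, r was -0.97 over 5 lines. Without LN18 r was -0.89, and the relation no longer passed (exact permutation, adjusted p = 0.122), whereas the other alternatives gave adjusted p between 0.00317 and 0.0444. The mesenchymal and proneural subtype lists had r = -0.69 (exact permutation p = 0.0758, adjusted p = 0.152) and rho = -0.68 (exact permutation p = 0.110, adjusted p = 0.146), and r was 0.01 without U87-MG and LN229, on which the value rested. Interferon response and antigen presentation class I genes had r = 0.18 (exact permutation p = 0.702, adjusted p = 0.702) and rho = 0.14 (exact permutation p = 0.783, adjusted p = 0.783), and r = 0.93 without U251-MG and LN18. Hypoxia response and glycolysis genes had r = 0.58 (exact permutation p = 0.179, adjusted p = 0.239) and rho = 0.79 (exact permutation p = 0.0480, adjusted p = 0.0960), and r = 0.62 without LN229 and A172. All arrays lay on 1 slide, with 4 in its first row and 3 in the next, and the cells came from 2 suppliers with 5 and 2 lines, and over the 5 lines of the first supplier alone r was -0.95 for p53 target and proliferation genes, -0.70 for the mesenchymal and proneural lists, 0.16 for interferon response and class I genes and 0.35 for hypoxia response and glycolysis genes, with no test. The second supplier had too few lines, and no correlation was calculated within the rows of the slide. In both rows p53 target and proliferation levels had opposite orders. From the highest p53 target level down, proliferation levels were -0.42, -0.23, 0.13 and 0.53 in A172, LN229, T98G and LN18. In U87-MG, U138-MG and U251-MG they were -0.38, 0.02 and 0.29.

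**Figure D5:**
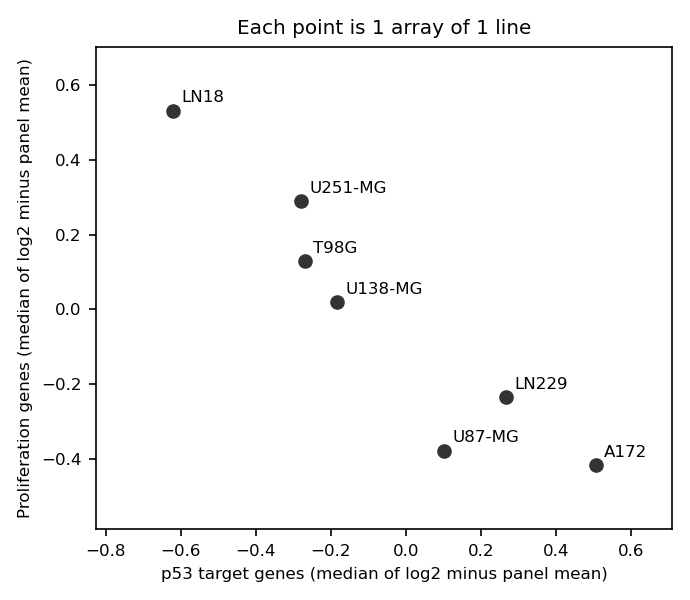
Each point is 1 array of 1 line, the horizontal axis gives the median of the p53 target genes and the vertical axis that of the proliferation genes, both as log2 minus the mean of the panel. LN18 lies at -0.62 and 0.53 and A172 at 0.51 and -0.42, with the other 5 lines between them on the horizontal axis.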

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

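Tests of neighbouring low genes and of the closeness of U87-MG and U138-MG, and the count of highest genes of LN18 above the highest floor, were chosen only after the result was seen. Of 40 measures examined for a line far from the other 6, 4 had one, and chance alone gives about 2. The 75th percentile of log2 intensity was 9.89 in LN18 and 8.56 in the nearest line, and the mean signal of negative controls was 76.3 in LN18 and 56.1 in the nearest line. The slope of the spike-in controls was 0.864 in LN229 and 0.974 in the nearest line. The squared correlation of that fit was 0.953 in LN229 and 0.984 to 0.991 in the other lines. Whether the response of this array affected the shifts in LN229 was not tested. The level of oligodendrocyte markers was 3.84 (log2, against the mean of the panel) in LN229 and 0.26 in the nearest line.

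Genes lowest in 1 line lay side by side in 38 pairs over the 7 lines, against at most 15 in 10000 random placements. Side by side means next to each other, by the positions of the files, among protein-coding genes above background in the other 6 lines. Other genes can therefore lie between them. Random placement treats genes as unrelated, whereas all U87-MG pairs were of zinc finger genes, and related neighbours can share probe sequence. Some neighbours had probes on 1 short stretch, as PKN3 and ZDHHC12 in U138-MG (131483128 to 131483218 of chromosome 9). So did CDCA7L and DNAH11 in LN229 (21940832 to 21940975 of chromosome 7). The 38 pairs are therefore not a count of independent signals. U87-MG (14 pairs, at most 6 at random) and A172 (6, at most 5) exceeded their own random maximum, U138-MG (9, random mean 1.58) and U251-MG (4, random mean 0.527) met it, and LN18, LN229 and T98G lay below it. A failed probe is argued against by 32 other probes of 25 such genes, lower by a median of -3.02 (log2, quartiles -4.80 and -1.77), 27 of them by at least 1. Probes at background in their line were not floored, so the sizes of their differences are not exact. The argument does not cover T98G (INTU, -0.90) or U251-MG (GALT, -0.09). A172 was mixed (CYP2R1 -0.60, ZNF302 -3.145, ZDHHC23 0.13, CREB3L2 -1.59). Loss of 1 of 2 copies, about 1 (log2), cannot be weighed here. The genes were chosen as at least 2 below every other line, and no copy number was measured. In U87-MG, 45.8% (11 of 24) of the zinc finger genes at 35 to 39 Mb of chromosome 19 that were above background in all 6 other lines were well above background. This argues against complete loss of the whole interval, not of a smaller segment. None of the 7 genes of the longest run (37676419 to 38123448) was above background on its brightest probe, and they were chosen as low. Another probe of ZNF527, a gene of that run, was above background (-0.27). In U138-MG, 1 of 3 probes of DCBLD1 and GOPC on chromosome 6 was above background, against complete loss at that probe alone. That DCBLD1 probe was still at -3.92 (log2) against the median of the other lines. Near these genes, RFX6 and ROS1 (117253134 to 117609672) lay side by side among the genes highest in U138-MG, named after their values were seen. On chromosomes X and 9, 0 of 10 probes of XIAP, STAG2, CAAP1, PLAA and IFT74 were above background. That count decides nothing, since these genes were chosen as low in U138-MG and the regions were parted after the result was seen. Silencing and structural change were not tested and stay open.

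The LN18 array was the brightest. Of the 12 lists called in LN18, 11 (91.7%) were called again in the same direction after quantile normalization. Over all lines 87 of 93 were, so the share does not set LN18 apart. The random lists were already matched on expression, so this weighs little against brightness as the source of those shifts. Quantile normalization also leaves the background correction as it was. Of the 12 lists, only interferon response (0.74) and epithelial markers (0.70) lay within the random lists with normexp. With 1 floor for all arrays LN18 had 255 highest genes in place of 387, a ratio of 1.52 that is close to the median ratio of the other lines (also 1.52). This decides nothing, since the count was also 255 with each array at its own floor. That match is fixed by construction, because U251-MG has the highest floor and LN18 is compared with it either way. Of the 387, 384 had signal in LN18 above the highest floor of the 7 arrays, so detection below that floor added few genes to its count. The share was similar in other lines, with 557 of 562 in U87-MG and 388 of 397 in LN229, and does not set LN18 apart. No biological explanation was tested.

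U87-MG and U138-MG lay close over the 1000 genes of highest SD (r = 0.39). They share a row of the slide with U251-MG, which correlated with U87-MG by 0.102 and with U138-MG by 0.129. Of the 35 splits of the arrays into 4 and 3, that of the rows included, 3 had a difference of correlations within and between groups as large as that of the rows (0.082), which with so few arrays decides nothing. A shared supplier is argued against, since the suppliers of this pair differ and the pair from the second supplier had r = 0.129, below the median of 0.163 over 21 pairs. An effect of the row of the slide stays open, and no biological explanation was tested.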

How the results depend on the processing

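The floor on values below background was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each line has 1 array. Except where construction is named, the cause was not tested. Of the 93 list shifts, 1362 values under alternatives divide into 824 that moved by less than their spread, 528 that moved further and 10 of opposite sign; of the 29 chromosome shifts, 435 into 299, 136 and 0; of 167 named genes, 2328 into 1500, 824 and 4. By construction, chromosome shifts cannot change with the floor or with only probes above background on all arrays. Named genes cannot change with that filter or with no background filter. Such values count among the 299 and the 1500. Signal over background limits these results, since a gene at background in some lines has only a bound for its fold. The median of all genes in LN18 lay at -0.15 (log2), at -0.51 with normexp and at -0.28 with the 75th percentile over probes above background on all arrays, which put U87-MG at 0.16, and normexp put U251-MG at 0.13.

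In the order U251-MG, U138-MG, U87-MG, T98G, LN229, LN18 and A172, highest genes numbered 125, 95, 171, 81, 169, 126 and 146 with normexp, 71, 38, 121, 46, 133, 72 and 100 in the table of the authors, and 34, 21, 40, 28, 55, 50 and 49 over probes above background on all arrays, where fewer genes enter. Lowest genes numbered 33, 43, 32, 16, 24, 76 and 32 with normexp and 31, 40, 29, 16, 20, 32 and 24 in the table of the authors. Over probes above background on all arrays they numbered 59 in A172, 25 in LN229, 23 in T98G, 35 in U87-MG, 54 in U138-MG and 36 in U251-MG, and highest and lowest genes together split into 277 and 342 (44.8% higher, against 77.6%). With the floor highest genes numbered 255 in LN18, 145 in T98G, 367 in U87-MG, 240 in U138-MG and 240 in U251-MG, and lowest 40 in T98G, 95 in U138-MG and 58 in U251-MG. With a line left out, fewer lines are compared, and lowest genes numbered 85 to 113 in LN229 (most without U251-MG), 81 to 123 in T98G (without LN18), 118 to 190 in U87-MG (without U138-MG) and 181 to 244 in U138-MG (without U87-MG).

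Correlations of LN18 and T98G, LN18 and U87-MG, LN18 and U251-MG, and U87-MG and U138-MG over all genes were 0.929, 0.889, 0.904 and 0.931 with normexp, 0.921, 0.879, 0.900 and 0.928 over probes above background on all arrays, 0.933, 0.903, 0.913 and 0.929 with no filter, 0.892, 0.841, 0.860 and 0.882 with Spearman's rho, and 0.924, 0.882, 0.898 and 0.922 with the floor. In the table of the authors they were 0.924 for LN18 and T98G, 0.875 for LN18 and U87-MG and 0.918 for U87-MG and U138-MG. Over the genes of highest SD, LN18 and T98G had 0.532 with normexp, 0.564 in the table of the authors and 0.633 over probes above background on all arrays, where LN18 and U87-MG had 0.305, LN18 and U251-MG 0.386 and U87-MG and U138-MG 0.559. LN18 and U251-MG had 0.181 in the table of the authors.

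List shifts called numbered 43 over probes above background on all arrays, where 60 of the 93 had enough members, and chromosome shifts 16 with normexp and 15 with no filter. The relation of p53 target and proliferation genes ranged from -0.984 to -0.885 with a line left out, the latter without LN18. Opposite in sign were 9p21 neighbours in T98G (-0.27 without LN18, -0.27 without U87-MG and -0.32 without U138-MG, up to 3.28 without LN229), astrocyte markers in LN229 (-0.25 over probes above background on all arrays, -0.077 against the mean, -0.093 with the floor), fibroblast and matrix genes in U251-MG (0.18) and NF-kB cytokine genes in A172 (0.066), LN229 (-0.10) and T98G (0.16) over probes above background on all arrays, EGFR in LN229 (0.75), RRM2 in LN18 (-0.21) and MRPL23-AS1 in U138-MG (-0.19) with the median of their probes, and EMCN in LN18 (0.061) in the table of the authors.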

Other observations

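All tests and all genes named in this part were chosen after their values were seen. Genes highest in 1 line lay side by side in 82 pairs, against at most 38 in 10000 random placements, and 6 lines exceeded their own random maximum while U251-MG (7, at most 9) did not. Here the genes ordered were protein-coding and above background in at least 1 line, so other genes can lie between neighbours. In T98G a run on chromosome 10 (5019910 to 5246455, hg19) held 4 aldo-keto reductase genes, AKR1C1, AKR1C3, AKR1C8 and AKR1C4. In LN18 a run on the X chromosome (134872077 to 134994053) held CT45A5, CT45A1, CT45A7 and SAGE1. In A172 a run on chromosome 19 (43576018 to 43764581) held the pregnancy-specific glycoprotein genes PSG2, PSG5 and PSG9, and in U87-MG a run on chromosome 4 (69696473 to 71031715) held UGT2B10, UGT2B7, UGT2B11 and PRR27. Related neighbours can share probe sequence, so a run of similar genes is not a count of independent signals.

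In U87-MG the 24 zinc finger genes at 35 to 39 Mb of chromosome 19 that were above background in all 6 other lines were lower than the median of the other lines by a median of 6.21-fold (-2.63 log2 at the floor), while 48 other genes of that interval chosen in the same way had a median of 0.07. Over the 34 zinc finger genes there that were above background in at least 1 line the median was -2.14 at the floor. Zinc finger genes elsewhere on chromosome 19 had a median of -0.75 (168 genes) and those on other chromosomes -0.33 (200 genes). In LN18 the same 24 genes had a median of 1.41. The longest run in U87-MG (37676419 to 38123448) held ZNF585B, ZNF383, ZNF875, ZNF527, ZNF569, ZNF571 and ZFP30.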
